A study of Homo sapiens with 12 samples.

How the data were processed

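Total RNA from cells labelled as MDA-MB-231, an established human breast cancer line without hormone receptors or HER2 amplification, was measured on 12 Affymetrix 3′ expression arrays. Per the labels, the cells had been stably transfected with a scramble shRNA, an shRNA against LSD2, an eGFP/Flag vector or an LSD2/eGFP/Flag vector, with 3 biological replicates in each of the 4 groups. Per the labels' protocols, G418 was added to kill untransfected cells, RNA was purified on columns with DNase digestion, and biotin-labelled cRNA was hybridised. The labels do not say whether each stable line was a clone or a pool. The p-values below measure the spread between the replicates, which may all come from 1 line per group, so a difference between groups is also a difference between lines.

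The authors deposited log2 values for 22277 probe sets, and the submitters' processing notes name RMA (background correction, quantile normalization and summary of the probes of a probe set). The software, its version and the probe annotation are not given in the sources used here. The deposited log2 values of the 6 shRNA arrays had medians from 6.65 to 6.71 and minima from 1.94 to 2.08, and those of the 6 vector arrays had medians from 7.03 to 7.18 and minima from 3.03 to 3.17. Because of this difference and of different numbers of printed decimals, the shRNA arrays and the vector arrays were treated as normalized separately. No gene was tested for a difference in level between them. The planned test of eGFP/Flag vector against scramble shRNA was therefore left out. Levels set across the shRNA and vector arrays served for correlations, counts and comparisons with shuffles, after quantile normalization of all 12 arrays where stated. These carry the limit that the arrays appear to have been normalized separately. RMA values carry no detection calls, so low values have no order, and the number of arrays limits the precision.

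Probe sets were named from the platform annotation, which can be old, and its gene identifiers were looked up in a RefSeq gene table of assembly GRCh38.p14. Of the probe sets, 62 were controls and 20113 were listed in the annotation. The annotation gave 1 gene for 19064 probe sets, several for 1043 and no listed gene for 2108. Of the 19064, 19052 matched the gene table and 12 kept the name of the annotation. Only probe sets naming 1 gene were used. For the 4310 genes with several probe sets the brightest over all 12 arrays was taken, which left 11964 genes. The gene table served only for names and for the order of genes along chromosomes. No probe set used here named KDM1B, the gene of LSD2 (0 probe sets), so the level of the targeted gene could not be used to check the labels.

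Differences were tested with limma 3.58.1 in R 4.3.3, with lmFit on the deposited log2 values, a mean for each group and all 12 arrays in 1 fit, and eBayes (8 residual and 4.82 prior degrees of freedom). Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes, and a gene was called at an adjusted p under 0.05. The contrasts were LSD2 shRNA minus scramble shRNA, LSD2/eGFP/Flag vector minus eGFP/Flag vector, and the difference between these effects. Values are given as log2 differences ± the standard error of the fit, or as group means ± SD (n = 3). On simulated arrays with known changes, the fit recovered 73.1%, 95.5% and 100% of the changes of 0.5, 1 and 2 log2 units in the shRNA comparison, with 5.29% of the calls false. In the vector comparison it recovered 76.1%, 97.0% and 100%, with 3.70% of the calls false. The simulated noise was normal and independent, as the fit assumes, and far fewer genes were changed than were called in the data. These shares check the procedure and do not estimate false calls in the real arrays.

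Before the data were examined, 32 gene lists with 851 symbols were fixed (733 measured), together with the rule for the genes named. Lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 32 lists of a comparison. Camera with a correlation estimated from the data and fry were alternatives. The rule named, for each comparison, the 8 largest rises and 8 largest falls among called genes whose 3 arrays per group did not overlap. It also named up to 3 called members per list with the largest differences, every measured member of the list of LSD2 partners and paralog, and the 5 genes per pattern called in both comparisons with the largest smaller difference. Uncharacterised loci and genes of the sex chromosomes used to tell sexes apart were not named. The other alternatives were a replicate block, a fit on the compared groups alone, cyclic loess, a shift to equal medians, leaving out the dimmest genes, the mean of all probe sets, an intensity trend, array weights, stricter thresholds and leaving out each array in turn. The HOX, keratin, S100 and annexin families, taken by symbol and counted, the division of the scramble arrays between calls and placement, the place of the eGFP/Flag line for genes called in both comparisons, and the order of called genes along chromosomes were chosen after the results were seen.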

Results

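LSD2, the product of KDM1B, is a histone demethylase that acts on lysine 4 of histone H3. The arrays ask which genes change in MDA-MB-231 breast cancer cells when LSD2 is lowered by a stable shRNA and when it is raised by a stable LSD2/eGFP/Flag vector. Gene expression was measured on 12 arrays, 3 each for scramble shRNA, LSD2 shRNA, eGFP/Flag vector and LSD2/eGFP/Flag vector, and 11964 genes were tested. Arrays of 1 group correlated closely over genes, with r from 0.996 to 0.998. No probe set used here named KDM1B, so the knockdown and the overexpression were not checked on the targeted gene.

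The arrays labelled LSD2/eGFP/Flag vector stood apart from all others. Their r was 0.904 to 0.908 with the eGFP/Flag arrays and 0.865 to 0.870 with the shRNA arrays. The eGFP/Flag arrays, in contrast, correlated with the scramble arrays at 0.943 to 0.950 and with the LSD2 shRNA arrays at 0.951 to 0.957, although the shRNA and vector arrays appear to have been normalized separately. Scramble and LSD2 shRNA arrays correlated at 0.991 to 0.994. These correlations are across genes, which are not independent replicates.

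**Figure D1:**
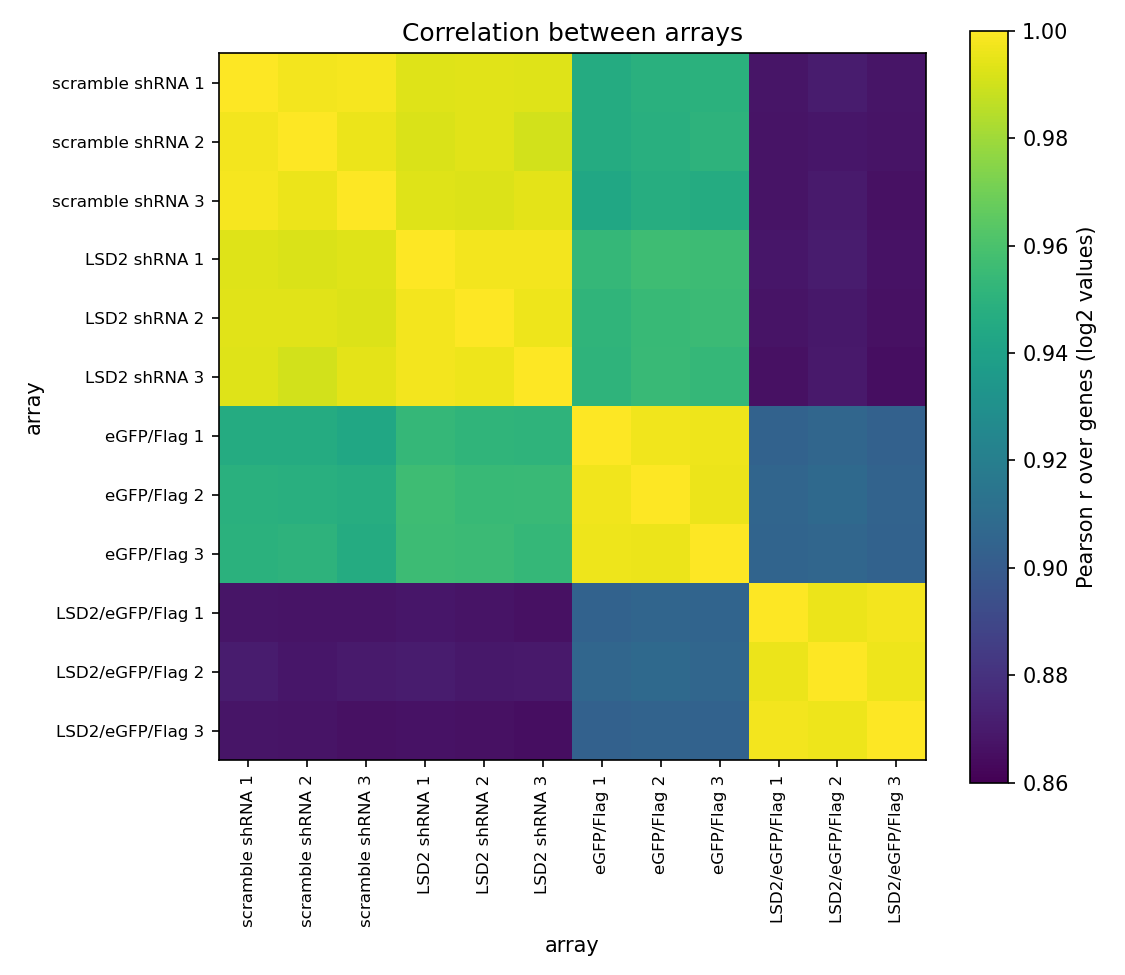
Pearson r over genes between each pair of the 12 arrays (log2 values), with arrays in the same order on both axes. The 3 arrays labelled LSD2/eGFP/Flag have r of 0.865 to 0.908 with the other 9, while those 9 have r of 0.943 or more with each other.

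The first comparison asks what changed with the LSD2 shRNA. CD96, an adhesion receptor best known from T and NK cells, rose by 4.02 ± 0.16 log2 units, from 4.89 ± 0.24 to 8.91 ± 0.32 (SD, n = 3), and the mesenchymal cadherin CDH11 rose by 3.84 ± 0.35. The sialyltransferase ST6GALNAC5 (3.27 ± 0.12), the interleukin-13 decoy receptor IL13RA2 (3.24 ± 0.23), the proteoglycan core protein SRGN (3.14 ± 0.23) and the cancer-testis gene MAGEB2 (2.89 ± 0.12) also rose, as did ADGRF5 (2.02 ± 0.37) and G0S2 (2.02 ± 0.14). Nonmuscle myosin heavy chain MYH10 fell by 2.00 ± 0.13, from 10.19 ± 0.23 to 8.19 ± 0.12. CLIC3 fell by 1.96, OLFML3 fell by 1.92, the mitochondrial isocitrate dehydrogenase IDH2 fell by 1.79, the chemokine CCL2 fell by 1.67, SLC2A10 fell by 1.54, the collagen gene COL5A1 fell by 1.51 and IGFBP7 fell by 1.47. The adjusted p of these 16 genes (limma, Benjamini-Hochberg) lay between 1.3e-08 for CD96 and 0.0064 for SLC2A10.

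**Figure D2:**
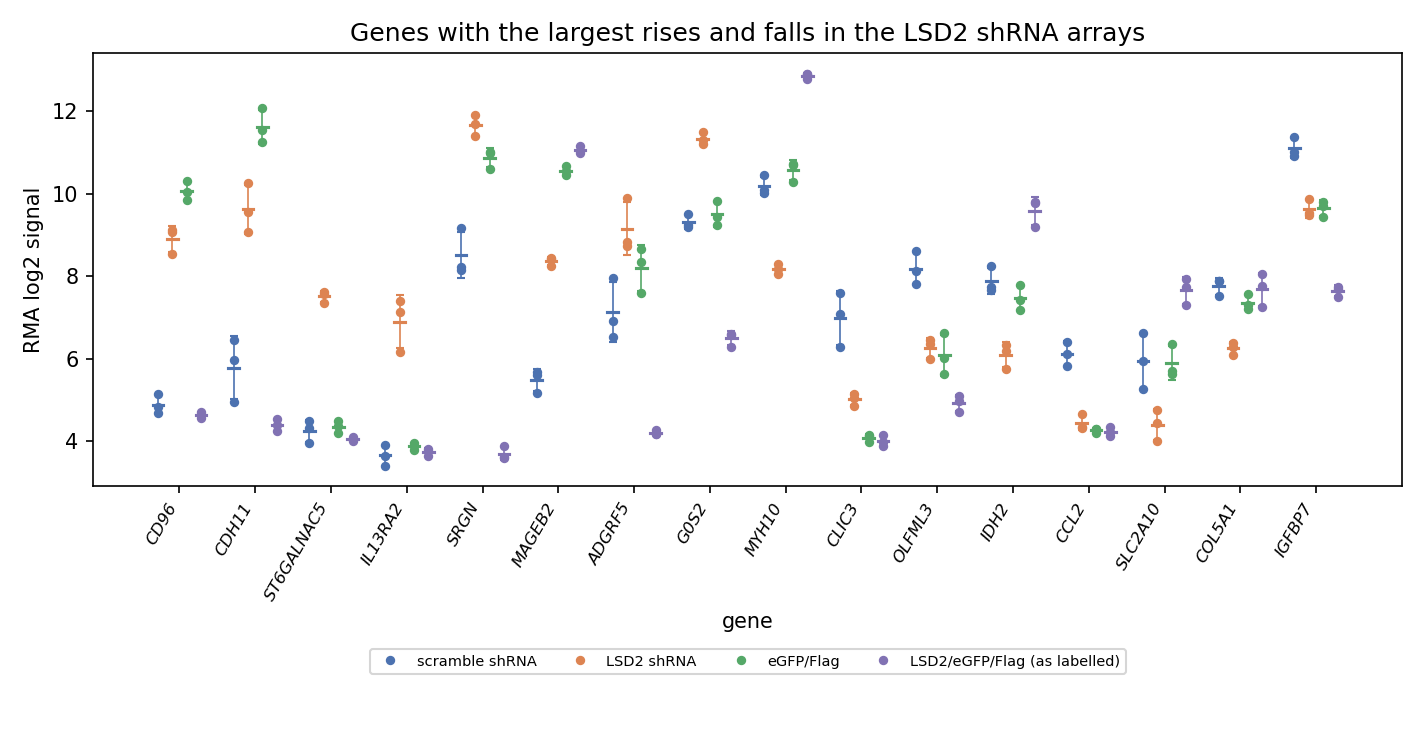
RMA log2 signal of the genes with the largest rises and falls in the LSD2 shRNA arrays (x axis, genes), with 1 point per array, a bar at the mean and whiskers of 1 SD (n = 3) for each of the 4 groups. The LSD2 shRNA arrays lie above the scramble arrays for the first 8 genes and below them for the last 8. CD96 in the eGFP/Flag arrays (10.07 ± 0.23) is also above scramble, although the shRNA and vector arrays appear to have been normalized separately.

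Of 24 measured ErbB ligands and MAPK feedback genes, 8 rose, 0 fell and 16 were not called (the same counts when adjusted over the list alone), among them the EGFR ligand EREG (1.63 ± 0.10), the ERK phosphatase DUSP6 (1.00 ± 0.24) and the feedback inhibitor SPRY2 (0.86 ± 0.12). The list was higher than other genes in limma's camera test with Benjamini-Hochberg adjustment (adjusted p = 0.000193), and the adjusted p was 0.932 with an estimated correlation. In the list of S phase genes, 5 of 39 rose and 0 fell (8 and 0 adjusted over the list alone), including the histone mRNA binding protein SLBP (0.45 ± 0.07), GINS3 (0.39 ± 0.07) and the licensing factor CDT1 (0.28 ± 0.07). Of 14 histone genes 3 rose and 0 fell (5 and 1 adjusted over the list alone), namely H1-2 (1.35 ± 0.16), H2BC12 (0.99 ± 0.12) and H2BC5 (0.48 ± 0.12). Of 25 ribosomal protein genes 2 rose and 0 fell (2 and 0 adjusted over the list alone), RPS25 (0.40 ± 0.10) and RPL14 (0.36 ± 0.07). Camera called these lists too, with adjusted p of 0.010 for S phase genes, 0.0155 for histones and 0.0258 for ribosomal proteins, and for each the adjusted p was 0.932 with an estimated correlation. The ribosomal list was not called after cyclic loess (0.473), with the dimmest genes left out (0.0517), or without scramble replicate 1 (0.0519), scramble replicate 2 (0.104) or LSD2 shRNA replicate 1 (0.211), its range over the camera alternatives being 0.00474 to 0.932. The calls of DUSP6 (without scramble replicate 1 or 3 or LSD2 shRNA replicate 1 or 2), CDT1 (scramble 2 or 3, LSD2 shRNA 1 or 3), H2BC5 (scramble 1 or 3, LSD2 shRNA 1) and RPS25 (scramble 1 or 2, LSD2 shRNA 1 or 2) were lost when those arrays were left out.

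The other 28 lists were not called in this comparison. None of the 8 measured genes listed as LSD2 partners or paralog was called (0 rose, 0 fell, and 0 adjusted over the list alone). Binding of the listed genes' products to LSD2 was not measured here. KDM1A, the paralog LSD1, was at 0.03 ± 0.07. The nucleosome-binding partner GLYR1 was at 0.25 ± 0.09 by its brightest probe set, and at -0.10 and -0.16 by others. Among chromatin regulators, 3 of 22 other histone demethylases fell (KDM5B by 0.67, KDM4B by 0.59, KDM4A by 0.32), NSD2 (0.35 ± 0.08) and SETMAR (0.53 ± 0.13) rose among 25 methyltransferases, 3 rose and 1 fell of 16 deacetylases and sirtuins, with HDAC9 up by 0.79 ± 0.14, and 0 of 13 DNA methylation genes were called. Of 28 mesenchymal genes 2 rose and 3 fell, with CDH11 up and COL5A1 and fibronectin FN1 down, the latter by 1.03. Of 29 matrix protease genes 4 rose and 3 fell, with ADAMTS1 (1.79 ± 0.21) and the collagenase MMP1 (0.94 ± 0.13, from a low 3.09 ± 0.20) up. Of 26 epithelial junction genes 1 rose, EPCAM (0.57 ± 0.13), and 2 fell, PKP3 (by 0.69) and CLDN4 (by 0.44). Among 21 stem cell markers 3 rose, KLF4 by 1.05 ± 0.16, and 1 fell, ABCG2 by 0.64. Of 31 NF-kB and cytokine genes 4 rose and 3 fell, with PTX3 (1.47 ± 0.21) and the prostaglandin synthase PTGS2 (1.00 ± 0.23) up and CCL2 down. Of 30 TGF-beta pathway genes 4 rose and 5 fell, with follistatin FST up by 1.27 ± 0.15 and INHBB down, which fell by 1.42. Adjusted over the list alone, these rises and falls were 3 and 3 for deacetylases, 3 and 3 for mesenchymal genes, 5 and 4 for matrix proteases, 1 and 3 for epithelial genes, 4 and 1 for stem cell markers, 5 and 4 for NF-kB genes and 5 and 7 for the TGF-beta pathway, with the others the same. The calls of KDM4A (without scramble replicate 1 or 2 or LSD2 shRNA replicate 1 or 2), KDM4B (scramble 2, LSD2 shRNA 3), NSD2 (scramble 2), SETMAR (scramble 1 or 2, LSD2 shRNA 1), EPCAM (scramble 2, LSD2 shRNA 1) and PTGS2 (LSD2 shRNA 2) were lost when those arrays were left out.

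Of 28 respiratory chain genes 5 fell and 1 rose (7 and 1 adjusted over the list alone), with the complex I subunits NDUFS1 (fell by 0.59), NDUFV1 (fell by 0.49) and NDUFS3 (fell by 0.44), and of 33 glycolysis and hypoxia genes 4 fell and 1 rose, led by adrenomedullin ADM, which fell by 1.08. SREBF1, a regulator of lipid synthesis, fell by 1.09 among 18 cholesterol synthesis genes, of which 2 fell and 1 rose. None of these lists was called by limma's camera test, the adjusted p (Benjamini-Hochberg) being 0.352 for respiratory chain, 0.410 for glycolysis and hypoxia and 0.964 for cholesterol synthesis genes. The counts of rises and falls were 2 and 0 of 25 immediate early genes (called by camera in the fit on the compared groups alone, adjusted p = 0.0329, and 0.932 with an estimated correlation), 1 and 0 of 29 stress response genes, 3 and 3 of 25 Wnt genes, 2 and 1 of 17 integrins, 6 and 4 of 40 G2 and M phase genes, 2 and 2 of 23 p53 targets, 0 and 3 of 28 apoptosis regulators, 2 and 1 of 33 interferon-stimulated genes, 0 and 0 of 20 antigen presentation genes, and 0 and 2 of 20 imprinted genes. Most markers of other cells or lines were not called, with 2 and 0 of 18 luminal markers, 1 and 0 of 16 basal markers, 1 and 1 of 20 blood cell markers and 1 and 1 of 20 fibroblast and endothelial markers. Adjusted over the list alone, rises and falls were 2 and 6 for glycolysis and hypoxia genes, 5 and 3 for Wnt genes, 3 and 1 for integrins, 7 and 6 for G2 and M phase genes, 0 and 3 for imprinted genes and 2 and 1 for luminal markers, with the others the same. The median, mean and camera direction differed in sign for LSD2 partners and paralog, histone demethylases, mesenchymal genes, integrins, G2 and M phase genes, p53 targets and cholesterol synthesis genes.

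In all, 1260 of 11964 genes were called (limma, Benjamini-Hochberg), 598 higher and 662 lower with the LSD2 shRNA, and 63 of them differed by at least 1 log2 unit. The balance of directions turned with the scaling, with 760 higher and 515 lower after a shift to equal medians and 660 higher and 626 lower after cyclic loess. The called genes were unevenly placed along the genome, as counted after the results were seen. On chromosome 3, 96 rose and 7 fell, while on chromosome 17, 12 rose and 115 fell, MYH10 and SREBF1 among them, and on chromosome 11, 17 rose and 107 fell. Each called gene and the next called gene on its chromosome, however many other genes lay between, shared their direction in 80.7% of cases. Directions shuffled over the whole genome 1000 times gave at most 55.3%. Such shuffles also undo the lean of whole chromosomes, so they cannot show that close neighbours moved together. For 41 of the 63 genes the eGFP/Flag line lay nearer to the LSD2 shRNA line than to the scramble line. This level was set, after quantile normalization, across arrays that appear to have been normalized separately, with the scramble arrays shared by the calls and the placement. The count of 1260 fell to 752 without scramble replicate 1, 832 without scramble replicate 2 and 774 without LSD2 shRNA replicate 1, and rose to 2352 with array weights. Without LSD2 shRNA replicate 1 the ErbB and MAPK list alone was called, the adjusted p being 0.0561 for histones and for S phase genes and 0.211 for ribosomal proteins.

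**Figure D3:**
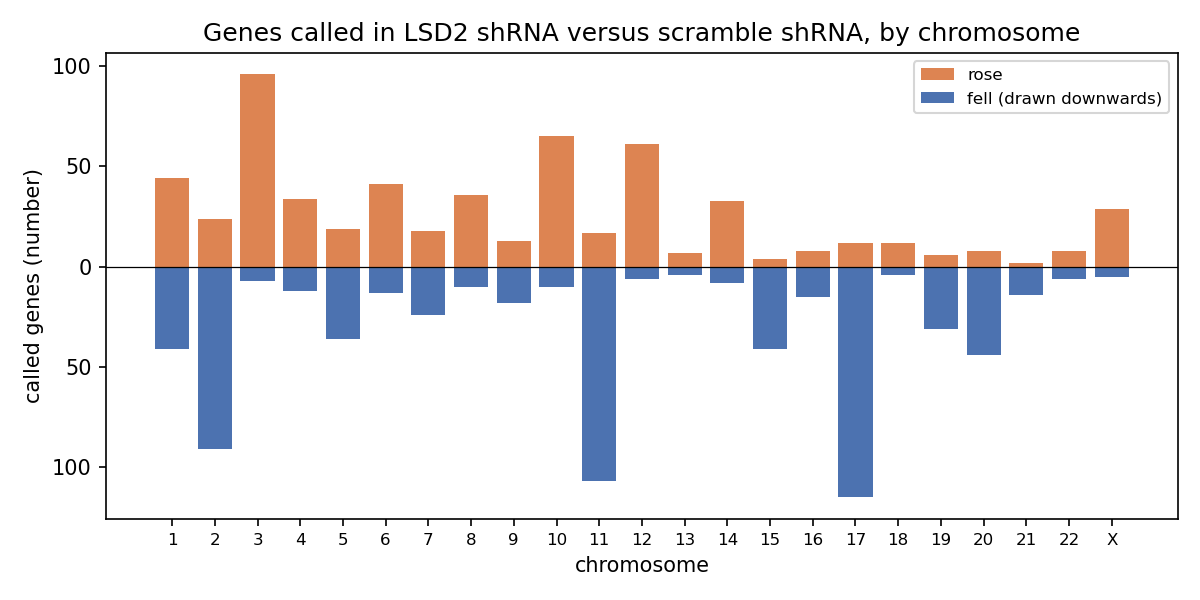
Number of genes called in LSD2 shRNA against scramble shRNA on each chromosome, with genes that rose drawn upwards and genes that fell drawn downwards. Chromosome 3 holds 96 rises and 7 falls, and chromosome 17 holds 12 rises and 115 falls.

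The second comparison asks what changed with the LSD2/eGFP/Flag vector, and its arrays are called here by their label. Many genes went from low to high signal or the reverse. Among the genes named, the largest rises were TMEM47 (7.34 ± 0.12), the imprinted zinc finger gene PLAGL1 (7.22 ± 0.10), the corepressor TLE4 (7.16 ± 0.13), cyclin CCND2 (6.93 ± 0.10), the neurofilament NEFM (6.74 ± 0.14), the retinoic acid synthesis enzyme ALDH1A2 (6.74 ± 0.15), BEX4 (6.67 ± 0.09) and the tubulin TUBB2B (6.48 ± 0.08). These are values of the brightest probe set. Other probe sets gave smaller rises for TLE4 (0.49 and 0.86), ALDH1A2 (0.59) and TMEM47 (1.74), while those of PLAGL1 gave 7.17 and 5.98. Annexin ANXA1 fell by 8.60 ± 0.08, from 13.25 ± 0.13 to 4.65 ± 0.06 (SD, n = 3), and the hyaluronan receptor CD44 fell by 8.42. The ectonucleotidase NT5E fell by 8.26, EMP1 fell by 8.22, EREG fell by 8.15, the actin-binding peptide gene TMSB4X fell by 7.86, the ErbB ligand NRG1 fell by 7.83 and DUSP6 fell by 7.61. The adjusted p of these genes (limma, Benjamini-Hochberg) was at most 1.0e-11, that of DUSP6. Between the eGFP/Flag arrays and these arrays, 47 genes went from above percentile 80 of their array to below percentile 33.3 and 32 the other way, against 0 and 1 between scramble and LSD2 shRNA.

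The next lists were called lower by camera in the arrays labelled LSD2/eGFP/Flag, whose r with their control was at most 0.908. Of 24 ErbB and MAPK feedback genes 20 fell and 3 rose (camera adjusted p = 3.2e-10 by limma, 0.103 with an estimated correlation). Of 33 interferon-stimulated genes 24 fell and 3 rose, among them IFI44 (fell by 5.94), OASL (fell by 3.43) and IFIT1 (fell by 3.39), with an adjusted p of 1.2e-06 by camera and an adjusted p of 0.103 with an estimated correlation. Of 16 basal markers 8 fell and 0 rose, including caveolin CAV1 (fell by 5.97), LAMB3 (fell by 5.73) and the receptor EGFR (fell by 4.56). Of 17 integrins 9 fell and 1 rose, including ITGA3 (fell by 3.61) and ITGA2 (fell by 2.55). Of 31 NF-kB and cytokine genes 14 fell and 2 rose, with LIF down, which fell by 4.44. The adjusted p by camera was 0.000743 for basal markers, 0.0144 for integrins and 0.0105 for NF-kB genes, and for each the adjusted p was 0.103 with an estimated correlation. Of 25 immediate early genes 12 fell and 3 rose, led by CCN2 (fell by 7.36) and FOSL1 (fell by 5.25). Of 29 matrix protease genes 14 fell and 6 rose (15 and 6 adjusted over the list alone). The largest falls there were CTSZ (fell by 5.33, but by 0.24 with another probe set) and the urokinase gene PLAU (fell by 5.22). For immediate early genes and matrix proteases the adjusted p was 0.0235 and 0.0320 by camera, and the adjusted p was 0.653 and 0.355 with an estimated correlation.

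Cell cycle lists were called in opposite directions in the same arrays, whose r with their control was at most 0.908. Of 40 G2 and M phase genes 31 fell and 6 rose, with MKI67 down, which fell by 2.01, and KIF23 down, which fell by 1.60 (camera adjusted p = 1.4e-05 by limma, and adjusted p = 0.395 with an estimated correlation). Of 39 S phase genes 22 rose and 6 fell (22 and 7 adjusted over the list alone), among them CCNE1 (1.64 ± 0.08), CDT1 (1.57 ± 0.07) and GINS3 (1.29 ± 0.07). Of 25 ribosomal protein genes 14 rose and 0 fell, led by RPL8 (0.97 ± 0.06). Their adjusted p was 0.0320 and 0.0144 by camera, and the adjusted p was 0.473 and 0.653 with an estimated correlation. Without LSD2/eGFP/Flag replicate 2, camera no longer called S phase genes (adjusted p = 0.0519), matrix proteases (0.0533) or immediate early genes (0.0735). Matrix proteases were also not called after a shift to equal medians (0.0517) or with the dimmest genes left out (0.106), nor S phase genes with the mean of all probe sets (0.0920). Over the camera alternatives the adjusted p ranged from 0.0193 to 0.473 for S phase genes, 0.0304 to 0.355 for matrix proteases and 0.00193 to 0.653 for immediate early genes. Except where given, the counts adjusted over the list alone were the same.

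The other 22 lists were not called. Of the 8 measured genes listed as LSD2 partners or paralog, GLYR1 (0.95 ± 0.09), EHMT2 (0.90 ± 0.09) and the paralog KDM1A (0.79 ± 0.07) rose. RCOR3 (by 0.36) and RCOR1 (by 0.33) fell, RCOR3 losing its call without eGFP/Flag replicate 1 or LSD2/eGFP/Flag replicate 1. The counts of rises and falls were 12 and 4 of 22 histone demethylases, 9 and 4 of 25 methyltransferases, 7 and 4 of 16 deacetylases, 3 and 6 of 13 DNA methylation genes and 4 and 5 of 14 histones. From the list of DNA methylation and demethylation genes, DNMT3B (2.50 ± 0.09) and TET1 (2.74 ± 0.21) were among the rises. They were 4 and 6 of 20 imprinted genes, with PEG10 (fell by 6.57) and MEST (fell by 5.55) opposite to PLAGL1, and 8 and 10 of 26 epithelial genes, with KRT7 (fell by 7.16) and KRT19 (fell by 5.22). Further counts were 5 and 9 of 21 stem cell markers, 11 and 10 of 28 mesenchymal genes, 11 and 15 of 30 TGF-beta genes, 9 and 9 of 25 Wnt genes, 9 and 5 of 23 p53 targets, 8 and 15 of 28 apoptosis regulators and 8 and 6 of 20 antigen presentation genes. They were 14 and 7 of 29 stress response genes, 6 and 14 of 33 glycolysis genes, 11 and 1 of 18 cholesterol synthesis genes and 15 and 3 of 28 respiratory chain genes. Marker lists gave 4 and 7 of 18 luminal, 1 and 3 of 20 blood cell, and 4 and 3 of 20 fibroblast and endothelial genes. Adjusted over the list alone, rises and falls were 7 and 5 for deacetylases, 8 and 11 for epithelial genes, 12 and 10 for mesenchymal genes, 9 and 6 for p53 targets, 9 and 15 for apoptosis regulators, 9 and 6 for antigen presentation genes and 16 and 3 for respiratory chain genes, with the others the same. The median, mean and camera direction differed in sign for mesenchymal, DNA methylation, histone, Wnt, and fibroblast and endothelial genes. Some of these lists were called by camera under alternatives. Cholesterol synthesis genes were called in the fit on the compared groups alone (adjusted p = 0.0259), after a shift to equal medians (0.0372), with array weights (0.0373) and without eGFP/Flag replicate 3 (0.0314). Epithelial genes were called with the dimmest genes left out (0.0341) and without eGFP/Flag replicate 3 (0.0433). Stem cell markers were called with the dimmest genes left out (0.0371), respiratory chain genes without eGFP/Flag replicate 3 (0.0362) and glycolysis genes without eGFP/Flag replicate 2 (0.0351). With an estimated correlation, the highest camera value for each, the adjusted p was 0.685 for cholesterol synthesis, respiratory chain and glycolysis genes, 0.231 for epithelial genes and 0.458 for stem cell markers. The CDK inhibitor CDKN2A rose by 4.82 ± 0.09, and its neighbours FOCAD and KLHL9, singled out after their values were seen, differed by 5.11 and 5.45.

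In all, 6824 of 11964 genes (57.0%) were called (limma, Benjamini-Hochberg), 3701 higher and 3123 lower in the arrays labelled LSD2/eGFP/Flag, with 2184 at least 1 and 207 at least 4 log2 units apart. After a shift to equal medians 3331 were higher and 3456 lower. All 3 arrays of the group stood apart, so no count without the arrays in doubt could be made.

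The last comparison asks whether raising and lowering LSD2 moved genes in opposite directions. CD96, CDH11, SRGN, ADGRF5 and G0S2 rose with the LSD2 shRNA and fell in the arrays labelled LSD2/eGFP/Flag, CD96 by 5.43 and CDH11 by 7.24. MYH10, IDH2, SLC2A10, SLC47A1 and IGFBP2 fell with the shRNA and rose in those arrays, MYH10 by 2.29 ± 0.13 and IGFBP2 by 4.60 ± 0.14. ADAMTS1, ZFPM2, IQCH, HMGA2 and STK26 rose in both, and IGFBP7, IL7R, OLFML3, MYL9 and FN1 fell in both. Called in both comparisons were 594 genes in opposite directions, against 361 for independent lists, and 366 in the same direction, against 358. By pattern, 324 rose with the shRNA and fell in the labelled arrays (156 for independent lists), 270 did the reverse (205), 132 rose in both (185) and 234 fell in both (173). Across genes, which are not independent replicates, the effects had a Pearson r of -0.165 and a Spearman rho of -0.0955. The directions also depend on where the eGFP/Flag control lay, as counted after the results were seen. The values were quantile-normalized across arrays that appear to have been normalized separately. This control was nearer to the LSD2 shRNA line than to the scramble line for 453 of the 594 genes in opposite directions (76.3%), CD96, CDH11, IDH2, SLC47A1 and IGFBP2 among them. The same held for 221 of the 366 in the same direction (60.4%). Among the other genes called in both, 141 had opposite and 145 the same direction. The eGFP/Flag arrays set both this placement and the effect in the labelled arrays, so the counts are not independent. The effects differed in 6029 genes (limma, Benjamini-Hochberg), 2363 of them by at least 1 log2 unit. The 594 fell to 376 without scramble replicate 1 and 383 without LSD2 shRNA replicate 1, and the 366 fell to 204 and 221, and to 240 without scramble replicate 2.

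**Figure D4:**
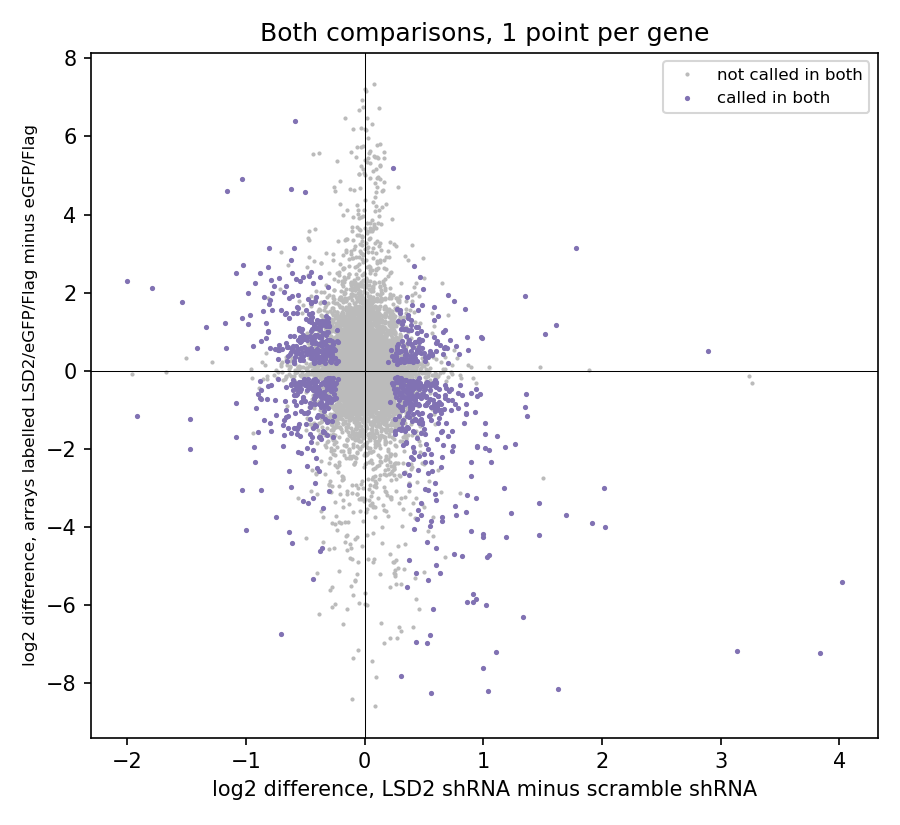
Log2 difference in the LSD2 shRNA comparison (x axis) against that in the arrays labelled LSD2/eGFP/Flag (y axis), with 1 point per gene and genes called in both coloured. The y axis spans a wider range than the x axis, and the correlation across genes is -0.165. A gene that the naming rule leaves out is not drawn.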

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

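No named gene and no list called under a setting had the opposite direction in the reported fit. Among genes this was checked for 101 in the shRNA comparison and 129 in the vector comparison, and not for the rest. Directions of lists that were not called did turn: fry gave the opposite direction to camera for integrins, p53 targets, NF-kB and cholesterol synthesis genes in the shRNA comparison, and for deacetylases and Wnt genes in the vector comparison. Array weights raised the LSD2 shRNA count to 2352, the opposite-direction count to 974 and the same-direction count to 701. Leaving out each array gave 752 to 1022 genes for LSD2 shRNA (lowest without scramble replicate 1), 376 to 625 in opposite directions, 204 to 381 in the same direction, and 1 to 4 called lists for LSD2 shRNA (1 without LSD2 shRNA replicate 1). The cause was not tested, beyond the smaller number of arrays. An adjusted p under 0.01, stricter by construction, left 564 genes for LSD2 shRNA, 267 in opposite and 140 in the same direction. Requiring 1 log2 unit left 63, 2184 and 2363 genes for LSD2 shRNA, the labelled LSD2/eGFP/Flag arrays and the difference between effects. With an estimated correlation camera called 0 lists in either comparison. Fry, which asks only whether a list moves, called 26 lists for the labelled arrays and 3 for LSD2 shRNA. These were the ErbB and MAPK list (fry adjusted p = 0.0312), histones (0.0312) and S phase genes (0.0326), while ribosomal proteins were not called (0.139). Deviations of arrays numbered 2 and of arrays numbered 3 correlated at 0.51 and 0.45 (shRNA) and at 0.17 and 0.18 (vector). Between numbers 2 and 3 they correlated at -0.48 and -0.46 (shRNA) and at -0.24 and -0.23 (vector). Deviations from a group mean sum to 0 over the 3 arrays, so the negative values are no separate evidence of pairing. Arrays numbered 1 correlated with each other at 0.02 and -0.14, so not every array correlated best with its own number. The replicate numbers may thus pair some arrays, which the reported fit ignores. A replicate block gave 1071, 6690 and 5871 genes. For single genes named in the shRNA comparison, 1284 results under the alternatives were on the same side of the threshold, 2 gained a call and 115 lost it, most often LYZ, DKK1, SQLE and EPAS1, with KDM4A, DUSP6, CDT1 and RPS25 among the others. In the vector comparison 1783 were on the same side, 2 gained a call and 2 lost it, both RCOR3. For lists, 499 were on the same side, 1 gained and 12 lost in the shRNA comparison, and 471, 25 and 16 in the vector comparison. The alternatives planned for KDM1B, and for eGFP/Flag against scramble, were not run, for want of a probe set and because of the apparent separate normalization. Signal over background limits genes with low RMA values.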

Other observations

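In this part, the gene families, the tests of separate normalization, of a response to LSD2, of differences between stable lines, of a stretch of chromosome 9, of other probe sets of CDKN2A and MTAP, of the placement of genes along chromosomes and of the division of the scramble arrays were chosen after the results were seen.

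Families picked by symbol, after some members had been seen among the largest changes, are given as counts with no test of the family. Of 24 HOX genes, which set position along the body axis, 17 rose and 2 fell in the arrays labelled LSD2/eGFP/Flag, led by HOXB6 (5.33 ± 0.13), HOXB7 (4.62 ± 0.08) and HOXD11 (3.17 ± 0.12). Of 11 annexins 8 fell and 0 rose, including ANXA3 (fell by 4.16) and ANXA2 (fell by 3.30). Of 17 S100 calcium-binding proteins 8 fell and 0 rose, of which S100A6 fell by 3.88 and S100A2 fell by 3.85. Keratins KRT8 (fell by 2.90) and KRT18 (fell by 1.83) fell with KRT7 and KRT19, among 32 keratins of which 8 fell and 1 rose. After a shift to equal medians the rises and falls were 16 and 3 for HOX genes, 0 and 9 for annexins, 0 and 12 for S100 genes and 0 and 15 for keratins. After cyclic loess they were 16 and 3, 0 and 8, 0 and 8, and 1 and 10. In the LSD2 shRNA comparison 1 HOX gene, HOXD4, fell by 0.58. S100A2 (0.65 ± 0.16) and ANXA10 (0.73 ± 0.11) rose there, and 0 keratins were called (1 fell after cyclic loess).

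The size of the difference in the arrays labelled LSD2/eGFP/Flag could have several causes. Separate normalization of the shRNA and vector arrays is argued against by the design, since both groups compared are vector arrays, with medians from 7.03 to 7.18. The lowest r between controls exceeded the highest r between eGFP/Flag and LSD2/eGFP/Flag arrays by 0.0353, which adds no separate test of it. Cells other than MDA-MB-231 stay a candidate explanation that the tests leave open: of CDKN2A, CDKN2B and MTAP, which this line is known to have lost, 1 (CDKN2A) was above the array median in all 3 labelled arrays by its brightest probe set, while the brightest probe sets of CDKN2A and MTAP reached percentiles 38.8 and 35.3 in the other arrays, above the bound of 33.3 set beforehand for lost genes. Other probe sets differed among themselves. For CDKN2A, 1 had means of 4.17 to 4.30 in the other groups and 10.55 ± 0.19 in the labelled arrays. For MTAP, 2 of 5 had 2.47 to 4.41 and 8.03 ± 0.17, and 4.11 to 4.47 and 7.06 ± 0.09. The other 3 of MTAP lay within 0.71 of the eGFP/Flag arrays. The brightest of them had means of 5.93 to 6.41 in the 4 groups. Its percentile of 35.3 therefore cannot tell whether MTAP was lost. CDKN2B (4.75 ± 0.05) and another of CDKN2A (5.04 ± 0.05) were low in the labelled arrays too. A probe set with much the same signal in every group cannot tell a lost gene from a silent one. If the cells of the other arrays lack CDKN2A and MTAP, more LSD2 could not give the signals that rose. For these genes those signals then argue against a response to LSD2. The neighbour FOCAD had means of 3.56 to 4.48 in the other groups and 9.59 ± 0.02 in the labelled arrays. The brightest probe set of KLHL9 had 4.36 to 5.44 and 10.89 ± 0.19. Both thus switched on too, and 10.8% of other runs of 38 genes held as many such genes. The run of neighbours left out CDKN2A, CDKN2B and MTAP and held interferon genes with low signal in every group. Its count therefore cannot decide whether a stretch of chromosome 9 is missing from the other cells. For other genes a response to more LSD2 stays open too, with KDM1B unmeasured. Of the 207 genes at least 4 log2 units apart, 157 were not called in the LSD2 shRNA arrays. A further 42 (20.3%) were called there in the opposite direction and 8 in the same direction. The eGFP/Flag control lay nearer to the LSD2 shRNA line for 453 of the 594 genes called in opposite directions. Its place alone favours opposite directions, so these counts cannot decide.

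The genes that differed by at least 1 log2 unit with the LSD2 shRNA may reflect differences between stable lines that do not follow LSD2. The eGFP/Flag line, in which no change of LSD2 was planned, lay nearer to the LSD2 shRNA line than to the scramble line for 65.1% of these genes (41 of 63), and as far on the opposite side for 2, with the scramble arrays shared by the calls and the placement. With different scramble arrays for the calls and for the placement, the share lay between 51.9% and 68.9% of 61 to 77 genes over the 6 ways to divide them (2 to 9 opposite), against at most 31.1% when the deviations of the eGFP/Flag line were shuffled over genes 1000 times. The shuffles drew deviations from all genes, not from genes that differ this much between lines. They therefore give no chance share for genes that vary this much. The levels compared cross arrays that appear to have been normalized separately. A part played by LSD2 in single genes, such as ST6GALNAC5 and IL13RA2, which were low in the eGFP/Flag arrays, stays untested.

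Genes called with the LSD2 shRNA often shared their direction with the next called gene on the chromosome, in 80.7% of cases. Directions shuffled over the genome 1000 times gave at most 55.3%, so placement by chance over the whole genome is argued against. The shuffles did not keep the lean of each chromosome, so they cannot show that close neighbours moved together. Regional differences between the lines, such as DNA copy number, are a candidate explanation: of 35 runs of 40 genes whose calls leaned one way, such as RPH3AL to RNF167 on chromosome 17 (34 falls, 0 rises), the eGFP/Flag line lay nearer to the LSD2 shRNA line in 80% and on the opposite side in 2, against at most 60% in 1000 shuffles over runs. The shuffles treat runs as independent and draw from all runs, not only from those that lean. For runs of 20 and 80 genes the shares were 100% of 19 and 76.5% of 34, against at most 68.4% and 70.6%. Calls and placement shared the scramble arrays there, and with calls made without 1 of them and placement with it alone, 77.3% to 81.8% of 11 to 22 runs of 40 genes and 71.0% to 85.7% of 21 to 31 runs of 80 were nearer, with shuffles reaching 81.8% and 71.0%. The eGFP/Flag line also lay below scramble on chromosomes 19 (median -0.30) and 22 (-0.26), where the shRNA comparison had medians of -0.03 and -0.003. Called genes there were 6 rises and 31 falls on chromosome 19 and 8 and 6 on chromosome 22. The line was below scramble on chromosomes 20 (-0.23), 17 (-0.20) and 16 (-0.16) too, and above it on 4 (0.24), 18 (0.21) and 3 (0.20). Part of its place may come from the apparent separate processing, and a regional effect of LSD2 on chromatin was not tested.

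For the counts of 1260 and 6824 genes, the 10 splits of the 6 arrays are too few to reach a share under 0.05, with the real split alone (1) giving as many and 0 genes at most in the others. For the 6029 genes whose effects differed, 1 of 100 drawn splits, the real one, gave as many and the highest other gave 5761. That count rests on the vector arrays, because the 13 draws that kept their split gave at least 5017 genes and the others at most 10. For a difference between the effects beyond the vector comparison itself, the splits leave chance open.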
